A study of Rattus norvegicus with 6 samples.

How the data were processed

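RNA was measured in liver sinusoidal endothelial cells, the fenestrated lining of the liver's capillaries, taken from rats and kept together with hepatocytes, stellate cells and macrophages in a perfused culture device. The cells were held for 48 h at a shear stress of 1.15 dyn/cm2 under either 1 mmHg (physiological) or 12 mmHg (pathological) of pressure, with 3 libraries per pressure. Samples were grouped by the pressure that the labels give. Replicates were numbered 1 to 3 within a group in deposition order, and these numbers name libraries. No label states a pairing. The sample numbers are 2, 11 and 22 for the physiological and 3, 9 and 23 for the pathological libraries. Neighbouring sample numbers thus fall on libraries with the same replicate number, so a shared preparation cannot be excluded.

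The authors deposited expected counts per gene, 1 library per file, which are estimated read counts before any normalization, per the file headers. STAR, RSEM and limma are named in the submitters' processing notes without versions. The genome build, the annotation and the use of strand are not given in the sources used here. RSEM divides reads that match several genes among them, so between 4.33% and 10.4% of the values per library were not whole numbers, and genes with near-identical copies are uncertain. Antisense and overlapping genes are uncertain as well.

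Expected counts were rounded to whole numbers. Counts were compared with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter and no covariate, which left 12742 of 32623 genes. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and all tests were two-sided. Levels are CPM, counts relative to the library's total, computed here from the deposited counts with TMM-scaled totals and given as mean ± SD over 3 libraries. Log2 fold changes are pathological against physiological, with 95% confidence intervals from the fit. For a gene at 0 in every library of a group, a fold was computed against a floor of 3 counts over that group, and for a gene with 1 count the ratio is given with its exact binomial interval. These intervals and floors cover counting error only.

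A set of 36 gene lists, fixed before the data were examined, was tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01. Each list was tested again with its estimated correlation, and with fry, which asks whether a list's genes move on balance in 1 direction. Of the list symbols, 825 matched a symbol in the files, 6 matched the first of several identifiers, 15 matched through synonyms in a RefSeq gene table of another assembly, which was used for names only, and 25 were not matched. Summed CPM of a list used unscaled totals.

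Named genes followed a rule fixed before the data were examined. The rule took genes past the threshold with groups that did not overlap, and, as none passed, the 5 with the smallest unadjusted p in each direction at a mean log2 CPM of at least 1. It also took the 2 members with the smallest p from each list and a fixed set of markers. Other genes named in the text were chosen after their values were seen, and the text says so.

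Library totals ran from 8925149 to 24025406 counts. No pair of libraries agreed within sampling noise, with a chi-square per degree of freedom between 74.9 and 1100. The alternatives were other scaling factors, other low-count filters, DESeq2 1.42.0, limma-voom with and without sample weights, a block of neighbouring sample numbers, other thresholds and leaving out each library. Alternatives on hepatocyte RNA content, with libraries divided at 10000 summed CPM of the hepatocyte list, were added after seeing the data.

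The edgeR test was tested on simulated counts for the pathological against physiological comparison, drawn from the means and totals of these libraries with 200 changed genes. At a dispersion of 0.05 it recovered 44.8% of 67 genes changed 2-fold and 100% of 67 changed 4-fold, with 6 unchanged genes called among 14290 tested. At the dispersions estimated from the 6 libraries it recovered 0 of 66 genes changed 16-fold, among 12437 tested. Nothing states that the libraries came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.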

Results

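Gene expression was measured by RNA sequencing in primary rat liver sinusoidal endothelial cells cultured for 48 h at 1 mmHg, the physiological sinusoidal pressure, or at 12 mmHg, a pathological pressure of the kind found in portal hypertension. In the device these cells were kept together with hepatocytes, stellate cells and macrophages. Each pressure had 3 libraries. Totals were 24025406, 17117840 and 8925149 counts for physiological replicates 1, 2 and 3, and 23754767, 23649036 and 11426299 counts for pathological replicates 1, 2 and 3. The comparison asks how raised pressure alters endothelial expression, mechanosensing included.

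The libraries differed widely in transcripts of other liver cells. Genes of the hepatocyte list summed to 361, 59757 and 40463 CPM in physiological replicates 1, 2 and 3, and to 603, 945 and 79327 CPM in pathological replicates 1, 2 and 3. Albumin (Alb, the main plasma protein of hepatocytes) stood at 44.7, 23600 and 16300 CPM in the physiological libraries and at 132, 337 and 28400 CPM in the pathological libraries. The stellate cell list summed to 1040, 5970 and 5230 CPM at physiological pressure and to 677, 584 and 8280 CPM at pathological pressure. Macrophage transcripts summed to 116 CPM in pathological replicate 2, against 1140 to 3300 CPM in the other libraries. The first principal component held 57.6% of the variance and placed physiological replicate 1 at -183.12 beside pathological replicates 1 and 2 at -179.79 and -164.41, with the other 3 libraries between 47.50 and 274.89. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.961 between physiological replicate 1 and pathological replicate 1, and 0.552 and 0.459 between physiological replicate 1 and the other libraries of its own group.

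**Figure D1:**
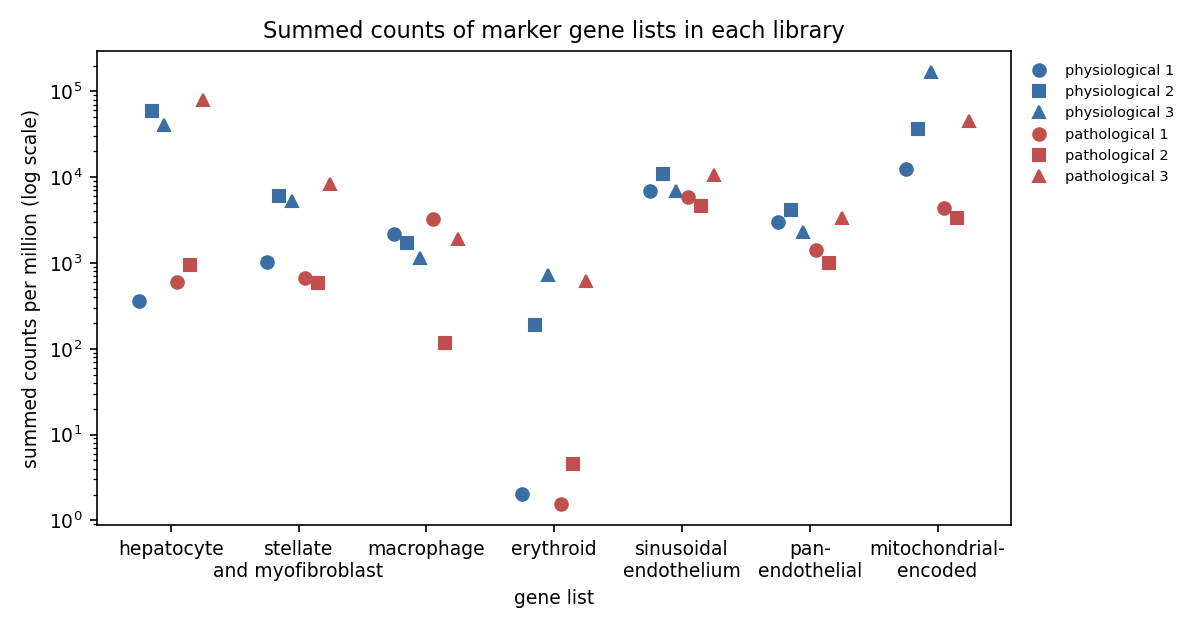
Summed CPM (log axis) of 7 gene lists in each of the 6 libraries, with 1 point per library, physiological in blue and pathological in red. The hepatocyte list lies between 361 and 945 in 3 libraries and between 40463 and 79327 in the other 3, in both pressure groups.

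No gene passed the threshold between the pressures. With edgeR's quasi-likelihood test, 0 of 12742 genes had a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 1. At an unadjusted p under 0.05 there were 33 genes, 7 higher and 26 lower at pathological pressure, where 637 would be expected by chance. The CPM values of the groups did not overlap for 588 genes, or 4.61%, where chance gives 10%. The biological coefficient of variation was 1.39, and the median standard error of a log2 fold change was 1.72. limma-voom also called 0 genes, with 159 at an unadjusted p under 0.05. With sample weights limma-voom called 0 genes as well, but far more than 637 genes had an unadjusted p under 0.05. The edgeR fit without pathological replicate 3 also had more such genes than expected by chance, and 0 past the threshold. Whether the unadjusted count lay below or above chance thus depended on how single libraries were weighted. DESeq2 called 45 genes, 10 higher and 35 lower, of which 23 had a count in 1 library and 34 were at 0 in every library of 1 group.

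Among the genes with the smallest unadjusted p on the higher side were the stress-inducible growth arrest gene Gadd45g (ENSRNOG00000013090) and the growth factor Hbegf (ENSRNOG00000018646), a ligand of the epidermal growth factor receptor. Gadd45g measured 112 ± 44.7 CPM at physiological and 440 ± 407 CPM at pathological pressure, a log2 fold change of 1.97 (95% CI 0.10 to 3.85, unadjusted p = 0.0411, edgeR adjusted p = 1). Hbegf measured 40.2 ± 14 and 159 ± 156 CPM, a log2 fold change of 1.98 (95% CI 0.01 to 3.95). Pathological replicate 2 held the highest value of both genes, at 908 CPM for Gadd45g and 339 CPM for Hbegf. The protease inhibitor A2m (ENSRNOG00000028896) had 443 counts at pathological pressure and 0 at physiological pressure, at least 135-fold higher, with 359 of the counts in pathological replicate 3. Hepacam2 and Galp were also at 0 in every physiological library and were at least 116-fold and 97.5-fold higher at pathological pressure, with 270 of 379 and 287 of 319 counts in pathological replicate 3. These bounds cover counting error only. The fit's 95% CIs on the log2 scale were 2.63 to 19.17 for A2m, 2.36 to 18.84 for Hepacam2 and 1.66 to 19.34 for Galp. The edgeR adjusted p of each of these genes was 1, and DESeq2 called Hepacam2 (DESeq2 adjusted p = 0.0117).

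On the lower side, the cyclin gene Ccnj (ENSRNOG00000014551) had 854 counts at physiological pressure and 1 at pathological pressure, a 931-fold difference with a counting interval of 167 to 36800. Pcp4l1 had 558 counts and 1 count, a 608-fold difference with an interval of 109 to 24100, and 507 of the 558 counts lay in physiological replicate 2. The tight junction gene Cgn (cingulin) and the fibroblast growth factor gene Fgf1 were at 0 in every pathological library and were at least 157-fold and 120-fold lower there. Physiological replicate 1, which was poor in hepatocyte transcripts, had 15 counts of Cgn and 21 of Fgf1, against 327 and 257 in physiological replicate 2. Ccdc152 measured 29.2 ± 23.9 CPM at physiological and 0.238 ± 0.298 CPM at pathological pressure. The edgeR adjusted p of each of these genes was 1, while DESeq2 called Ccnj, Cgn, Fgf1, Pcp4l1 and Ccdc152 with DESeq2 adjusted p of 0.000226, 0.00668, 0.00864, 0.0115 and 0.0323.

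Genes that respond to shear or sense force did not pass as groups over the 6 libraries. In the KLF2 and shear response list, 9 of 21 tested genes had positive and 12 negative fold changes, with a median of -0.23, a mean of 0.04, a test that pointed downward and a camera adjusted p of 0.763. Klf4, a flow-induced transcription factor of endothelium, measured 68.2 ± 22 CPM at physiological and 167 ± 73.2 CPM at pathological pressure, a log2 fold change of 1.29 (95% CI -0.20 to 2.78), and its groups did not overlap. Its paralog Klf2 had a log2 fold change of -0.48 (95% CI -3.63 to 2.67). Nos3, the endothelial nitric oxide synthase, measured 48.5 ± 24.4 and 27.7 ± 37.5 CPM. The vasoconstrictor gene Edn1 measured 6.08 ± 5.27 and 5.13 ± 4.53 CPM. Hmox1 (heme oxygenase) measured 2330 ± 485 and 5910 ± 5550 CPM, with 11800 CPM in pathological replicate 2 and 708 CPM in pathological replicate 3. In the mechanosensor list, 9 of 24 genes were positive, with a median of -0.30 and a camera adjusted p of 0.81. Plxnd1, a flow-sensing semaphorin receptor, measured 82.4 ± 31 and 43.1 ± 33.1 CPM. The YAP and TAZ target list had a median of -0.08 and a mean of -0.31 although its test pointed upward, with a camera adjusted p of 0.733. None of these 3 lists had a member past the threshold over all genes or adjusted over the list alone. With only the 3 libraries poor in hepatocyte transcripts, chosen after seeing the data and with 1 physiological library, the medians of these 3 lists were -0.57, -0.74 and -0.86, with camera adjusted p of 0.0126, 0.00057 and 0.00158 (adjusted p = 0.607 with an estimated correlation). The spread in that fit comes from the 2 pathological libraries alone, so it does not establish a decrease.

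Endothelial identity genes lay lower at pathological pressure as groups. In the pan-endothelial list, 23 of 25 tested genes had negative fold changes, with a median log2 fold change of -0.75 and a camera adjusted p of 0.000122 (adjusted p = 0.355 with an estimated correlation). Myct1 measured 41.7 ± 18.8 CPM at physiological and 12.3 ± 2.6 CPM at pathological pressure. In the sinusoidal endothelium list, 23 of 30 genes were negative, with a median of -0.55 and a camera adjusted p of 0.00342 (adjusted p = 0.355 with an estimated correlation). The hyaluronan receptors Lyve1 and Stab2 measured 1190 ± 814 and 129 ± 107 CPM at physiological pressure, and 711 ± 1130 and 74.1 ± 113 CPM at pathological pressure. Both followed the hepatocyte content of the library, with Lyve1 at 248 CPM in physiological replicate 1 and 2020 CPM in pathological replicate 3. Bmp2, which signals to hepatocytes in iron control, measured 99.7 ± 35.2 and 36.3 ± 7.4 CPM, a log2 fold change of -1.46 (95% CI -3.02 to 0.11). In the list of capillarized or continuous endothelium, 19 of 22 genes were negative, with a median of -1.05 and a camera adjusted p of 0.00617 (adjusted p = 0.355 with an estimated correlation). Esm1, a proteoglycan of activated endothelium, measured 71.5 ± 68.9 and 3.93 ± 5.15 CPM, and Vwf (von Willebrand factor) measured 25.5 ± 34 and 12.3 ± 12.3 CPM. Without physiological replicate 2, pathological replicate 1 or pathological replicate 2, the calls were lost, with camera adjusted p of 0.0526, 0.114 and 0.0834 for the pan-endothelial list, 0.116, 0.126 and 0.3 for the sinusoidal list, and 0.0689, 0.0911 and 0.14 for the capillarized list, which was also lost without physiological replicate 1 (0.111). With 1 library left out, the medians ran from -2.27 without pathological replicate 3 to -0.33 without pathological replicate 2 for the pan-endothelial list, and from -1.62 to -0.15 without the same libraries for the sinusoidal list. The capillarized median ran from -1.82 without pathological replicate 3 to -0.67 without physiological replicate 2. With only the 3 libraries rich in hepatocyte transcripts, an alternative chosen after seeing the data and with 1 pathological library, the pan-endothelial, sinusoidal and capillarized medians were -0.05, 0.06 and -0.29, with camera adjusted p of 0.612, 0.898 and 0.949 and a median of all genes of -0.58. With only the 3 libraries poor in them, chosen likewise and with 1 physiological library, the pan-endothelial, sinusoidal and capillarized medians were -1.33, -0.67 and -1.60, with camera adjusted p of 1.06e-12, 0.00057 and 1.33e-12 (adjusted p = 0.607 with an estimated correlation). With a term for hepatocyte content, also chosen after seeing the data, the sinusoidal call was lost (camera adjusted p = 0.223) at a median of -0.54, against -0.55 without the term. That term moved the median of all genes from 0.05 to -0.29, so relative to all genes the sinusoidal median went from -0.60 to -0.25, the pan-endothelial from -0.81 to -0.43 and the capillarized from -1.10 to -0.64.

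Secreted signals followed the same direction, although 14 of the 34 matched genes of the angiocrine list also stood in other lists. Rspo3, for example, was in both the Wnt and the sinusoidal list. The list of angiocrine and growth factors had 24 of 29 genes negative, with a median of -0.51 and a camera adjusted p of 0.00759 (adjusted p = 0.355 with an estimated correlation). The Wnt and R-spondin list had 8 of 13 genes negative, with a median of -1.27 and a camera adjusted p of 0.0459 (adjusted p = 0.355 with an estimated correlation). Rspo3, an enhancer of Wnt signalling, measured 19.9 ± 15.5 CPM at physiological and 1.46 ± 2.24 CPM at pathological pressure. The inflammatory cytokine list had 26 of 32 genes negative, with a median of -0.49 and a camera adjusted p of 0.0078 (adjusted p = 0.355 with an estimated correlation). The monocyte chemokines Ccl2 and Ccl7 did not overlap between the groups. Ccl2 measured 167 ± 52.2 and 66.5 ± 20.2 CPM, a log2 fold change of -1.33 (95% CI -2.77 to 0.11). Ccl7 measured 28.9 ± 6.35 and 4.81 ± 1.61 CPM, a log2 fold change of -2.59 (95% CI -5.35 to 0.18). The antigen presentation list had 14 of 17 genes negative, with a median of -0.99 and a camera adjusted p of 0.00101 (adjusted p = 0.355 with an estimated correlation). The extracellular matrix list had 24 of 34 genes negative, with a median of -0.54 and a camera adjusted p of 0.0266 (adjusted p = 0.355 with an estimated correlation). The antigen presentation genes summed to 1580, 8210 and 5420 CPM in the physiological and 1930, 1720 and 7700 CPM in the pathological libraries, higher in those rich in hepatocyte transcripts. With a term for hepatocyte content, chosen after seeing the data, all 5 calls were lost, with camera adjusted p between 0.0637 and 0.258. The medians with that term were -0.89 for the angiocrine, -1.24 for the Wnt, -0.65 for the inflammatory, -0.75 for the matrix and -0.54 for the antigen presentation list. Relative to all genes, whose median that term moved from 0.05 to -0.29, they went from -0.56 to -0.60 for the angiocrine, from -1.33 to -0.955 for the Wnt, from -0.54 to -0.37 for the inflammatory, from -0.59 to -0.46 for the matrix and from -1.04 to -0.25 for the antigen presentation list. The calls of these 5 lists were also lost without physiological replicate 2 or pathological replicate 2, with camera adjusted p between 0.103 and 0.236 and between 0.0834 and 0.522, and those other than antigen presentation were lost without pathological replicate 1 (0.0911 to 0.114). The angiocrine, Wnt and matrix calls were also lost without physiological replicate 1 (0.0803, 0.116 and 0.233), and the Wnt call without pathological replicate 3 (0.178). Without physiological replicate 2 the Wnt median was 0.03 and the antigen presentation median -0.10, and without pathological replicate 3 the angiocrine, inflammatory, antigen presentation and matrix medians were -1.51, -1.09, -2.48 and -1.03. The matrix call was also lost with a filter of CPM above 1 in at least 3 libraries (camera adjusted p = 0.124).

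**Figure D2:**
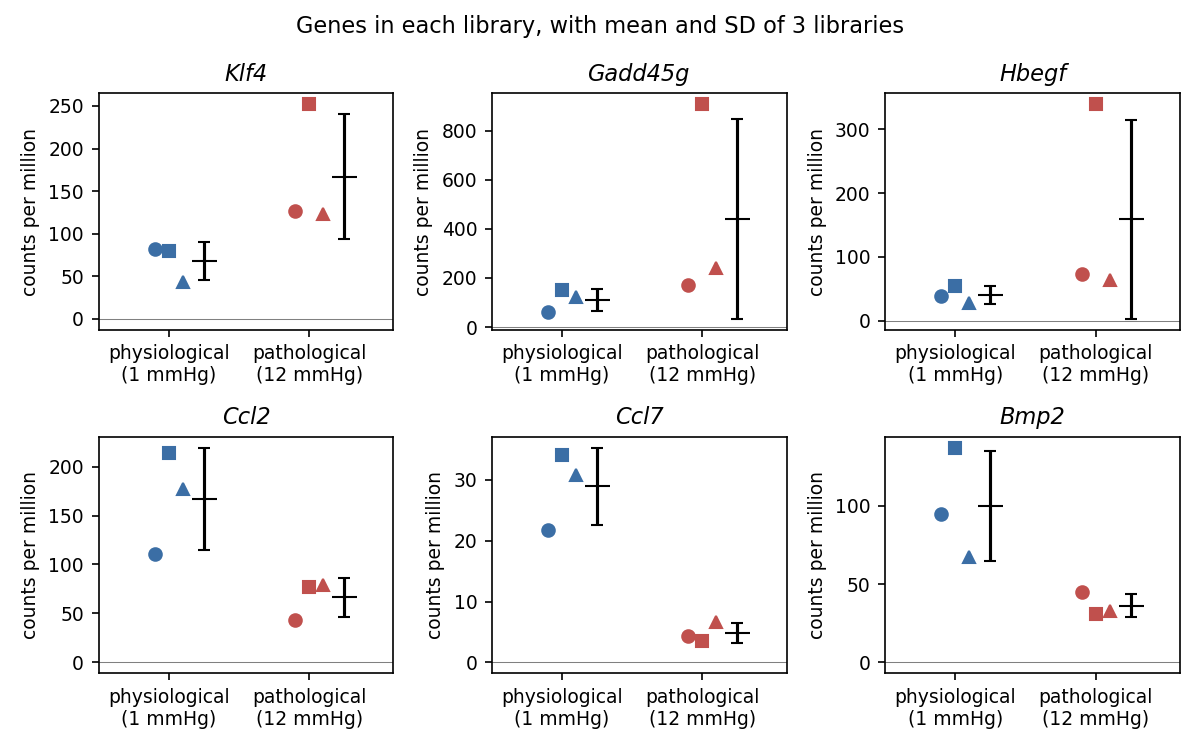
CPM in each library for 6 genes named by the fixed rule, shown because their groups did not overlap, with 1 point per library (circle, square and triangle for replicates 1, 2 and 3), a horizontal mark for the mean and bars for the SD of 3 libraries. Ccl7 measured 28.9 ± 6.35 at 1 mmHg and 4.81 ± 1.61 at 12 mmHg, and none of the 6 genes passed the edgeR adjusted threshold.

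Transcripts of the mitochondrial genome were lower at pathological pressure, with 12 of 12 genes negative, a median log2 fold change of -1.49 and a camera adjusted p of 8.57e-09 (adjusted p = 0.355 with an estimated correlation). Mt-co1, a subunit of cytochrome c oxidase, stood at 5750, 13500 and 127000 CPM in the physiological libraries and at 2370, 2380 and 13100 CPM in the pathological libraries. Without physiological replicate 3 the list's median was -0.29 with a camera adjusted p of 0.0172, and without pathological replicate 3 it was -4.38. Nuclear genes of oxidative phosphorylation had a median of -0.09 and a camera adjusted p of 0.733, and the direction of this list depended on single libraries. The median was -0.74 (camera adjusted p = 8.67e-05) without pathological replicate 3, -0.34 (0.0204) without physiological replicate 1 and 0.23 (0.025) without physiological replicate 3. With a term for hepatocyte content, chosen after seeing the data, it was 0.36 (7.08e-06). None of these 4 fits passed with an estimated correlation, with adjusted p between 0.519 and 0.789.

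Immediate early genes were the 1 list past the threshold on the higher side, with 19 of 24 genes positive, a median of 0.65 and a camera adjusted p of 0.00806 (adjusted p = 0.355 with an estimated correlation). Btg2, an antiproliferative early response gene, measured 118 ± 69.5 CPM at physiological and 258 ± 129 CPM at pathological pressure. Zfp36, which promotes decay of cytokine transcripts, measured 205 ± 51.5 and 379 ± 124 CPM. The call was lost without physiological replicate 1, physiological replicate 2, pathological replicate 2 or pathological replicate 3, with camera adjusted p of 0.294, 0.0689, 0.15 and 0.178, and the median was 0.35 without pathological replicate 2.

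Marker lists of other cell types also lay lower. The stellate cell list had 23 of 27 genes negative, with a median of -0.81 and a camera adjusted p of 2.03e-05 (adjusted p = 0.355 with an estimated correlation). Pdgfrb, the platelet-derived growth factor receptor of stellate cells, measured 27.9 ± 29.6 and 0.467 ± 0.451 CPM, and Col1a1 measured 22.4 ± 24 and 12 ± 12.7 CPM. The hepatocyte list had 32 of 36 genes negative, with a median of -0.46 and a camera adjusted p of 0.00342 (adjusted p = 0.772 with an estimated correlation). The macrophage list had 13 of 23 genes negative, with a median of -0.06 and a camera adjusted p of 0.015 (adjusted p = 0.698 with an estimated correlation), and Cd68 measured 85.6 ± 32.4 and 94.7 ± 89.5 CPM. The epithelial and junction list had 14 of 19 genes negative, with a median of -0.59 and a camera adjusted p of 0.00218 (adjusted p = 0.355 with an estimated correlation). The cholangiocyte and mesothelium list had 6 of 9 genes negative, with a median of -0.82 and a camera adjusted p of 0.0182 (adjusted p = 0.355 with an estimated correlation). Krt19, a bile duct keratin, measured 17.5 ± 19.7 and 0.388 ± 0.346 CPM. Without physiological replicate 2 or pathological replicate 2, the hepatocyte, macrophage, epithelial and cholangiocyte calls were lost, with camera adjusted p between 0.0952 and 0.978 and between 0.0834 and 0.79. Without pathological replicate 3 the hepatocyte, stellate, epithelial and cholangiocyte medians were -5.50, -4.05, -2.51 and -2.66, and without physiological replicate 2 they were 0.08, -0.26, -0.25 and -0.17. The macrophage median was 0.53 without pathological replicate 2. Without pathological replicate 1, the calls of the stellate, hepatocyte, epithelial and cholangiocyte lists were lost, with camera adjusted p between 0.087 and 0.468. The hepatocyte call was also lost without physiological replicate 3 (0.523), the macrophage call without physiological replicate 1 (0.0519), and the cholangiocyte call without physiological replicate 3 (0.0661) or pathological replicate 3 (0.178). With a term for hepatocyte content, chosen after seeing the data, the stellate median was -0.29, as was the median of all genes, and the call was lost (camera adjusted p = 0.949). The macrophage, epithelial and cholangiocyte calls were lost with that term as well (camera adjusted p = 0.486, 0.223 and 0.443), at medians of -0.27, -0.46 and -2.47, or 0.02, -0.175 and -2.18 relative to all genes. The cholangiocyte call was also lost with a filter of CPM above 1 in at least 3 libraries (camera adjusted p = 0.124).

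**Figure D3:**
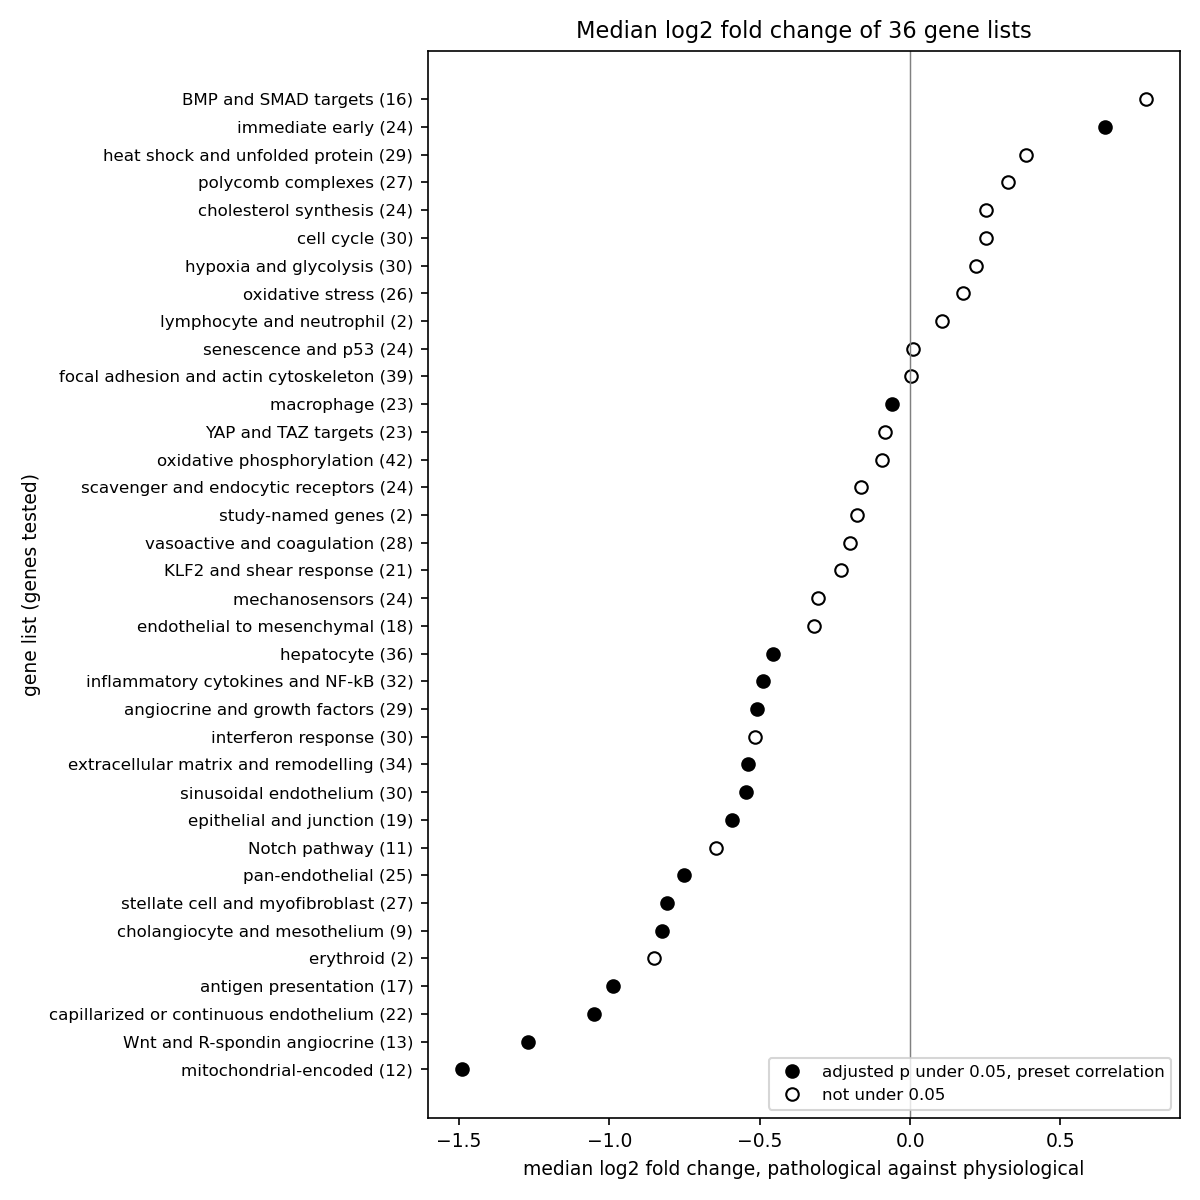
Median log2 fold change of each of 36 gene lists (horizontal axis, pathological against physiological), with the number of genes tested in parentheses and filled points for a camera adjusted p under 0.05 at the preset correlation. The mitochondrial-encoded list lies lowest at -1.49, and 0 lists passed with an estimated correlation.

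In total, 15 of 36 lists passed with the preset correlation, 14 lower and 1 higher, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.355. No list had a member past the threshold over all genes or adjusted over the list alone. The count was 2 without physiological replicate 2, 4 without pathological replicate 1 and 2 without pathological replicate 2. Lists shared genes, so their calls are not independent of each other. Of the matched genes, 15 of 32 in the sinusoidal, 12 of 27 in the capillarized and 14 of 32 in the stellate list stood in other lists. The mitochondrial-encoded and hepatocyte lists shared none. With fry, 1 list passed, focal adhesion and actin cytoskeleton, at an adjusted p of 0.0281, although its median was 0.00277 and its mean -0.16, with 20 genes positive and 19 negative and a camera adjusted p of 0.679. The angiocrine and epithelial lists each held 1 gene at 0 in a whole group, Fgf1 and Cgn, whose fold lies below the list's median either as fitted or as a bound, so the medians are -0.51 and -0.59 in both cases. Tpm4, a tropomyosin, measured 322 ± 33.4 and 199 ± 16.5 CPM. By camera, the BMP and SMAD, Notch, vasoactive, interferon, heat shock, oxidative stress, hypoxia, cell cycle, senescence, cholesterol synthesis, endothelial to mesenchymal, scavenger receptor, erythroid and lymphocyte lists did not pass, with adjusted p between 0.0653 and 0.742. Some of them passed with 1 library left out, although not with an estimated correlation. These were the heat shock list without physiological replicate 3 (camera adjusted p = 0.0206) or pathological replicate 3 (0.00929), the vasoactive list without physiological replicate 3 (0.0301), the interferon and erythroid lists without physiological replicate 1 (0.00261 and 0.0493) or pathological replicate 3 (2e-05 and 0.00484), the lymphocyte list without physiological replicate 1 (0.0038), and the endothelial to mesenchymal list without pathological replicate 3 (0.0259). Hes1, a Notch target, measured 29.2 ± 18.9 and 96.8 ± 62.2 CPM, and the proliferation marker Mki67 measured 8.2 ± 5.98 and 6.51 ± 7.49 CPM.

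The study's own work names the polycomb gene Cbx7, the cadherin gene Cdh1 and the secreted trypsin inhibitor gene Spink1. They may have been chosen on these samples, so they are not counted as independent evidence. Cbx7 stood at 7.70, 43.2 and 0 CPM in the physiological libraries and at 3.43, 0.284 and 70.2 CPM in the pathological libraries, a log2 fold change of 0.54 (95% CI -4.64 to 5.72). Cdh1 measured 17.2 ± 23.6 and 9.28 ± 14.3 CPM, a log2 fold change of -0.89 (95% CI -6.09 to 4.31). Spink1 had 1 count, in pathological replicate 3, and 0 in the other libraries, so a difference was not detectable at this depth, and the endothelial progenitor marker Cd34 was also too low to be tested. The polycomb list had 19 of 27 genes positive, with a median of 0.32 and a camera adjusted p of 0.753. The list of study-named genes had 2 tested members and a camera adjusted p of 0.733. With 1 library left out, its median ran from -3.59 without pathological replicate 3 to 1.96 without physiological replicate 2.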

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

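The alternatives on hepatocyte RNA content were chosen only after the results were seen. The count of 0 genes past the threshold was the same under both other scalings, both other filters, limma-voom with and without weights, the leave-one-out fits, both other thresholds, the hepatocyte term and covariate, and with only the 3 libraries low in hepatocyte RNA. It was 45 with DESeq2 and 244 with only the 3 libraries high in hepatocyte RNA, where 76 of the genes were at 0 in the lone pathological library, which is assumed to vary like the physiological ones. The cause was not tested. Against 15 lists, 6 passed with the hepatocyte term, 21 with only the libraries low in hepatocyte RNA, 2 with only those high in it, 13 with the CPM filter, which lost the matrix and cholangiocyte calls (0.124 each), 0 with an estimated correlation, 1 with fry, and 2 to 17 with 1 library left out. The direction of camera is relative to other genes, so it can turn while a list's fold changes stay negative. With only the libraries high in hepatocyte RNA, where the median of all genes was -0.58, it turned for the sinusoidal endothelium (camera adjusted p = 0.898), pan-endothelial (0.612), inflammatory (0.988), antigen presentation (0.9), stellate (0.988) and macrophage (0.501) lists, although the pan-endothelial, inflammatory, antigen presentation and stellate medians were -0.05, -1.02, -0.12 and -0.41. It turned for the stellate (0.775) and cholangiocyte (0.664) lists with only the libraries low in it, and for the stellate list (0.949, median -0.29) with the hepatocyte term. The hepatocyte list turned in those 3 fits too (0.000855, 2.81e-18 and 3.44e-20), but it defines the division of the libraries, so these values carry no evidence on its direction. Leaving out 1 library turned the hepatocyte list in 3 fits (0.468 to 0.978) and the macrophage list without pathological replicate 2 (0.3). Over these omissions the hepatocyte list spanned 7.28e-21 to 0.978 and the macrophage list 5.77e-05 to 0.3. The cause of these turns was not tested. Of 81 tested named genes, 34 had a fold of opposite sign in at least 1 alternative. With neighbouring sample numbers as a block, 0 genes and 14 lists passed, 13 of them among the 15, with the Wnt (0.118) and cholangiocyte (0.0576) calls lost and erythroid gained (0.0144, but adjusted p = 0.602 with an estimated correlation, over 2 tested genes). The deviations of such neighbours correlated at 0.642, -0.214 and 0.391 for replicates 1, 2 and 3. Both replicates 1 and both replicates 3 correlated best with their neighbour, and both replicates 2 did not. Both replicates 1 were poor and both replicates 3 rich in hepatocyte RNA, while replicates 2 differed in it. These correlations therefore cannot tell a pairing from shared hepatocyte content, and a pairing stays open. In simulations at the estimated dispersions, 0 of 66 genes changed 16-fold were recovered, so the spread between libraries limits these results. Low genes such as Spink1, with 1 count, could not be tested.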

Other observations

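The tests of gene counts over splits, hepatocyte content, mitochondrial transcripts and endothelial lists were chosen only after the results were seen, and Hspa1a, Cfb, C1qa and Cdh5 in the next paragraph were chosen after their values were seen.

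The endoplasmic reticulum chaperone gene Hspa5 was highest in pathological replicate 2. It stood at 2590, 1060 and 740 CPM in the physiological libraries and at 3720, 10400 and 397 CPM in the pathological libraries. The heat shock list had 22 of 29 genes positive, a median of 0.38 and a camera adjusted p of 0.13, and this rested on single libraries. It passed without physiological replicate 3 (camera adjusted p = 0.0206) or pathological replicate 3 (0.00929), though not with an estimated correlation (adjusted p = 0.647 and 0.462). Without pathological replicate 2 its median was 0.07 and its test pointed downward (0.9). Counts of near-identical genes lay on different copies in different libraries. Hspa1a stood at 0, 118 and 143 CPM in the physiological and 0.0715, 0.0947 and 103 CPM in the pathological libraries, while its copy Hspa1b stood at 1370, 703 and 500 CPM and at 3450, 5230 and 296 CPM. One Cfb entry (ENSRNOG00000051158) had 498 and 310 CPM in physiological replicates 2 and 3 and 0 in pathological replicate 3, where the other Cfb entry (ENSRNOG00000000419) had 537 CPM. The macrophage complement gene C1qa stood at 2.65 CPM in pathological replicate 2 and at 44.8 to 216 CPM in the other libraries. The vascular cadherin gene Cdh5 ranged from 184 to 320 CPM over the 6 libraries.

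With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. For genes past the threshold, the real value was 0, which all 10 splits must reach, so that count decides nothing, and the highest other split gave 2520. That highest split set physiological replicate 1 and pathological replicates 1 and 2 against the other libraries, which points to a structure of the samples that crosses the pressures. For gene lists, the real value was 15, the highest other split gave 16, and 2 of the 10 splits gave as many as the real one.

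Transcripts of hepatocytes were abundant in physiological replicates 2 and 3 and pathological replicate 3 and scarce in the others. The former also had the smaller totals, 8925149 to 17117840 counts against 23649036 to 24025406. Depth alone did not make the difference. Thinned to 8925136 counts, the rich libraries had 10008 to 12521 genes with a count, against 13308 to 16337 in the poor ones. The 20 most abundant genes held 14.7% to 28.2% of the counts in the rich and 8.24% to 14.1% in the poor libraries. Added hepatocyte RNA alone would dilute endothelial genes. The mean log2 CPM of the sinusoidal endothelium list was compared in 9 pairs of a rich and a poor library. It was higher in the rich library in 9 of 9, by 0.31 to 2.47. These means used TMM-scaled totals, which can offset dilution, so the pairs cannot decide on it. The TMM factor was 1.27 in physiological replicate 1, but 0.79 in physiological replicate 3 and 0.929 in pathological replicate 3. Unscaled, the list summed to 6970, 10900 and 6960 CPM in the physiological libraries and to 5860, 4570 and 10700 CPM in the pathological ones. With scaling, the pan-endothelial list was higher in 8 of 9 pairs, and the capillarized, angiocrine and macrophage lists in 4, 3 and 4 of 9. The stellate list was higher in 9 of 9, which concerns another cell type and not dilution of endothelial genes. The erythroid list followed the same division, at 2.04, 191 and 733 CPM in the physiological and 1.56, 4.48 and 614 CPM in the pathological libraries. The pairs that scaling did not favour rest on a single poor library, pathological replicate 2, so added hepatocyte RNA stays open as an explanation. A difference in cell state or in preparation may also underlie the division and stays open. The endothelial cells were kept together with hepatocytes, stellate cells and macrophages, but the design names nothing that divides the libraries this way. No biological explanation was therefore tested.

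Mitochondrial-encoded transcripts were lower at pathological pressure. Without physiological replicate 3, which held the most, the list's mean log2 CPM differed by -1.6 with a standard error between libraries of 1.52, so that library's part cannot be told apart from pressure. With a term for hepatocyte RNA content the difference was -1.55 with a standard error of 0.71. The call was kept at the preset correlation (camera adjusted p = 8.25e-06) but not with an estimated one (adjusted p = 0.776). Relative to all genes, that term moved the list's median log2 fold change from -1.54 to -0.915. With only the libraries rich in hepatocyte RNA the median was -0.557, or 0.0271 relative to all genes. With only the poor libraries it was -1.83, or -1.73 relative to all genes. Each of these 2 fits leaves 1 library in a group, so a part for unequal content stays open. Judged first by the spread over genes, which treats correlated genes as independent, the medians were -0.29 (standard error 0.33) without that library and -1.20 (standard error 0.549) with the term. An effect of pressure also stays open.

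Endothelial lists lay lower at pathological pressure, where 2 of 3 libraries were poor in hepatocyte RNA against 1 of 3 at physiological pressure. With a term for that content the pan-endothelial mean log2 CPM differed by -0.838 with a standard error between libraries of 0.651, too wide to exclude unequal content. The pan-endothelial and capillarized calls were kept with the term at the preset correlation (camera adjusted p = 0.0208 and 0.00722) and not with an estimated one (adjusted p = 0.776), and judged first by the spread over genes the pan-endothelial median of -0.71 (standard error 0.269) had seemed to exclude that explanation. A lower share of endothelial cells would raise the hepatocyte, stellate and macrophage lists, which instead differed by -1.27, -1.82 and -1.25 on the log2 scale, but with standard errors of 3.5, 1.56 and 1.49, so 0 of 3 were lower by more than 2 standard errors and the explanation stays open. Reduced endothelial expression under pressure remains a hypothesis beside these.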
